A study of Drosophila melanogaster with 2 samples.

How the data were processed

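Chromatin immunoprecipitation with an anti-GFP antibody was followed by sequencing in whole embryos of a transgenic line that expresses CG12744 with a C-terminal GFP tag. Per the labels, embryos of both sexes were collected at 0 to 24 h, chromatin was sonicated and fragments of 200 to 800 bp were used. The labels number the 2 samples as biological replicates 2 and 4 of 1 group, and a control is named in the records but was not used here.

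The authors deposited peak lists for the builds dm6 and dm3, in narrowPeak format. For each build there are 4 lists. There is 1 per replicate and 1 pooled list derived from the alignments of both replicates with a control, per the deposited text records. The last is a thresholded list made from the others by the irreproducible discovery rate, per the deposited records. This method weighs how alike peaks rank in replicates. Each single peak of the list need not do so: 78 thresholded peaks had no summit within 100 bp among the 2758 highest peaks of either replicate. The replicate and pooled lists hold 30000 peaks each, and most of them are background kept as input for that step. The peak signal is the deposited signal value of the authors' peak caller, and its scale is not stated. Signals were used only to rank or describe peaks within a list. The lists also carry the deposited −log10 of a q value, which has a single value of 3.83 at every thresholded peak and so was not used to rank them. The peak caller and aligner are not given in the sources used here. The 2758 thresholded peaks have the same signals as the 2758 highest peaks of the dm6 pooled list (9.19% of it), and cover 1025977 bp, 0.766% of the 6 chromosome arms named in the dm6 lists. Read depth is unknown from these files. Intervals given for shares are exact 95% binomial intervals (Clopper-Pearson) over peaks or genes, cover counting error only and do not include the variation between embryo collections.

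The dm6 lists were used throughout, with the Release 6 genome sequence and the Ensembl release 115 annotation, which share this build. The dm3 lists were used only for counts, replicate overlap and signals by rank, since no dm3 sequence, annotation or length table was used here. The dm3 thresholded list holds 2776 peaks, and over 2758 ranks its signals differed from those of dm6 by a median of 0.165% and at most 0.834%. Transposable element records were left out of the annotation, and every annotated transcript start was taken as a start site. Coordinates are 1-based.

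Replicates were compared by counting thresholded summits with a summit within 100 bp among the N highest peaks of each replicate, N being 2758, and by Spearman and Pearson correlation of log10 signal over peaks found in both lists. Chance overlap came from 1000 random rotations of the peaks along their own chromosome. A promoter peak is one whose summit lies within 500 bp of a start site, and a gene counts as bound when this holds for any of its start sites. The 33 gene lists, from gene symbols, symbol patterns and gene classes, and the 21 motifs were fixed before the data were examined, as were the tests and the alternatives. Exceptions are named where the text says that a choice was made after seeing the data. Members were compared with all other protein-coding genes on the 6 arms, or with all other genes for the RNA classes, by 2-sided Fisher's exact tests. Chromosome Y, planned as an arm, is not among the sequences of the dm6 lists and was not tested. Arms were compared with their share of length and of distinct start sites by exact binomial tests. Motifs were searched on both strands within 100 bp of the summit and in 1 flank window per peak, 1000 bp to a side chosen at random, and tested on discordant peaks by an exact binomial test. All 8-base sequences were counted once per window and compared with both flanks by Fisher's exact tests. Each family of tests was adjusted by Benjamini-Hochberg with a threshold of 0.05, and odds ratios and the ratios of 8-base sequences have 0.5 added to each count.

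The named genes were set by a rule fixed before the data were examined: the genes nearest to the 15 highest thresholded peaks, up to 4 members with the highest promoter peaks of each list past the threshold and up to 2 of each other list, CG12744 itself, and the 5 motifs and 5 8-base sequences with the largest increases. CACTG and CAACACTG were singled out after seeing the data.

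Alternatives were the 1379 peaks with the highest signal, each replicate alone, other summit distances and overlap rules, promoter windows of 250 and 1000 bp, other backgrounds and control sequences, other window sizes and sequence lengths, and the dm3 lists. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used. The statistics were tested on simulated data. Over 50 runs with bound genes drawn at random from 18164 genes, 2% gave any list past the threshold, and a list of 73 genes with 3 times the odds of other genes was recovered in 68% of runs. Left and right flanks of the real peaks gave 0 8-base sequences and 0 motifs past the threshold, and a sequence planted in 2.97% of 2758 windows ranked first. The overlap alternatives that compare peak intervals used 100 rotations. A planted overlap of 30.0% was recovered as 30.1%.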

Results

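The binding of CG12744, assayed here as a transcription factor, was mapped by chromatin immunoprecipitation and sequencing in whole Drosophila melanogaster embryos aged 0 to 24 h, of both sexes mixed. The flies carried a transgene in which the protein has a C-terminal green fluorescent protein (GFP) tag. The tagged protein was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates, numbered 2 and 4 in the labels. No other condition was present. The design therefore allows a description of where peaks lie and a comparison of the replicates, and no comparison between conditions. The deposited lists hold 2758 thresholded peaks on the dm6 genome build, a pooled list of 30000 peaks and 1 list of 30000 peaks for each replicate. The number of reads per library is not known from these lists.

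The highest peaks lay at promoters and in introns of a mixed set of genes. The peak with the highest deposited signal, 1147.69, had its summit at position 481089 of chromosome 2L, in an intron of ush, a cofactor of GATA factors. The nearest start site, 1401 bp away, was that of the zinc finger gene cbt. The next peaks were at CG14100 (3L, summit 19590633, between genes, 109 bp upstream of the start site) and in an intron of CG11050 (2L, summit 6612711). Then came Ugalt, a UDP-galactose transporter (X, summit 2703881, 29 bp upstream), and an intron of px, a wing vein gene (2R, summit 22514303). These were followed by an intron of Lk6, a kinase gene, by Art3, an arginine methyltransferase gene, and by lncRNA:CR44619. The Art3 peak also lay 137 bp from the start site of mRpS10. The Polycomb group gene ph-p, PNPase, mRpL41, CG1888, CenG1A, the chromosomal protein gene Chro and CHMP2B completed the 15 highest peaks. All 15 ranked within the first 17 peaks of both replicates. Signals fell steeply below them, to a median of 99.1 and a minimum of 68.4 over the thresholded list. In this list 31 peaks exceeded a signal of 500.

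The tagged gene itself carried a thresholded peak. CG12744 (FBgn0033459) spans 9874889 to 9876242 on the plus strand of 2R, and its peak spanned 9874988 to 9875397. The summit, at 9875193, lay in the 5' UTR of the gene and 88 bp upstream of the nearer of its annotated start sites. The deposited signal was 137, which is rank 715 of the thresholded list. The replicates differed in its height, with rank 437 in replicate 2 and rank 2878 in replicate 4.

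The replicates shared most of the thresholded peaks. Of the 2758 peaks, 2259 (81.9%) had a summit within 100 bp among the 2758 highest peaks of replicate 2 and 2194 (79.6%) among those of replicate 4. A summit in both was found for 1773 peaks (64.3%, exact 95% interval 62.5 to 66.1%), against a mean of 0.229% and a maximum of 0.58% over 1000 random rotations of the peaks along their chromosomes (1-sided permutation p = 0.000999, the smallest that 1000 rotations can give). Because the thresholded list was made from both replicates and their pool, the replicates were also compared directly. In this comparison, 1751 of the 2758 highest peaks of replicate 2 (63.5%) lay within 100 bp of one of replicate 4. Over the 2604 thresholded peaks present in both whole lists, the signals of the replicates had a Spearman rho of 0.605 and a Pearson r of 0.723 on the log10 scale (permutation p = 0.000999 for rho). These correlations are across peaks, which are not independent replicates.

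Agreement between the replicates depended on the height of the peak. In the pooled list, 98.4% of ranks 1 to 500 were matched in both replicate lists, against 68.6% of ranks 2759 to 10000 and 3.13% of the last 10000. The share of peaks at start sites fell with rank as well, from 64% of the first 500 to 22% of the last 10000.

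**Figure D1:**
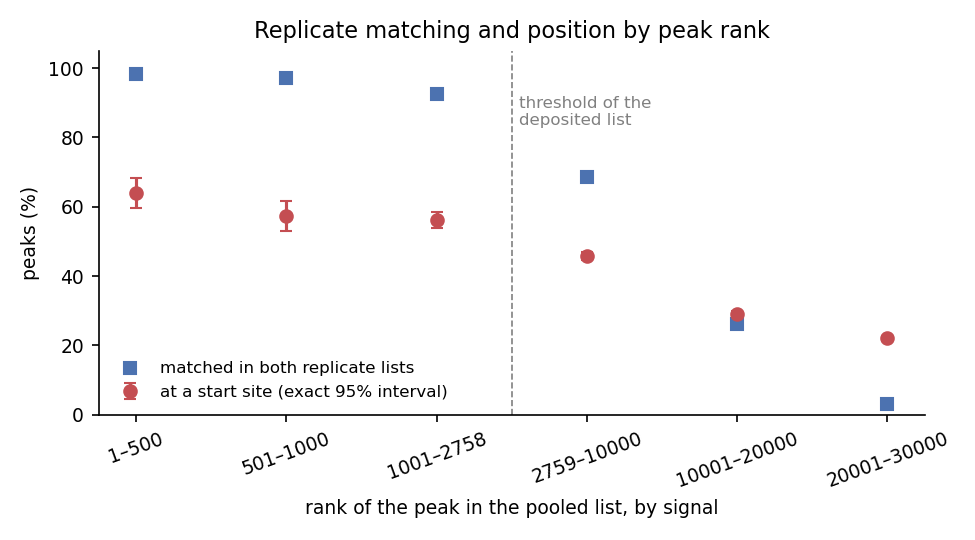
Peaks of the pooled list grouped by rank of deposited signal (x axis), with the percent matched within 100 bp in both replicate lists (squares) and the percent within 500 bp of a start site (circles, bars are exact 95% intervals). Matching falls from 98.4% in ranks 1 to 500 to 3.13% in the last 10000.

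CG12744 peaks were concentrated at promoters, just upstream of start sites. Of the 2758 summits, 1596 (57.9%, exact 95% interval 56.0 to 59.7%) lay within 500 bp of an annotated transcription start site, against a mean of 13.6% and a maximum of 16.1% over 1000 sets of random positions on the same chromosomes (1-sided permutation p = 0.000999, the smallest possible). Introns outside promoters held 29.3% of summits, against 39.4% of random positions, and intergenic sequence held 10.5% against 27.4%. Coding exons outside promoters held 6 summits, 0.218% against 13.9% of random positions, and 3' UTRs held 0.798% against 4.28%. Among the promoter summits 1279 lay upstream of the nearest start site and 313 downstream, so that 80.3% of these were upstream (exact interval 78.3 to 82.3%). The median position was 88 bp upstream, with quartiles at 168 and 22 bp upstream.

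**Figure D2:**
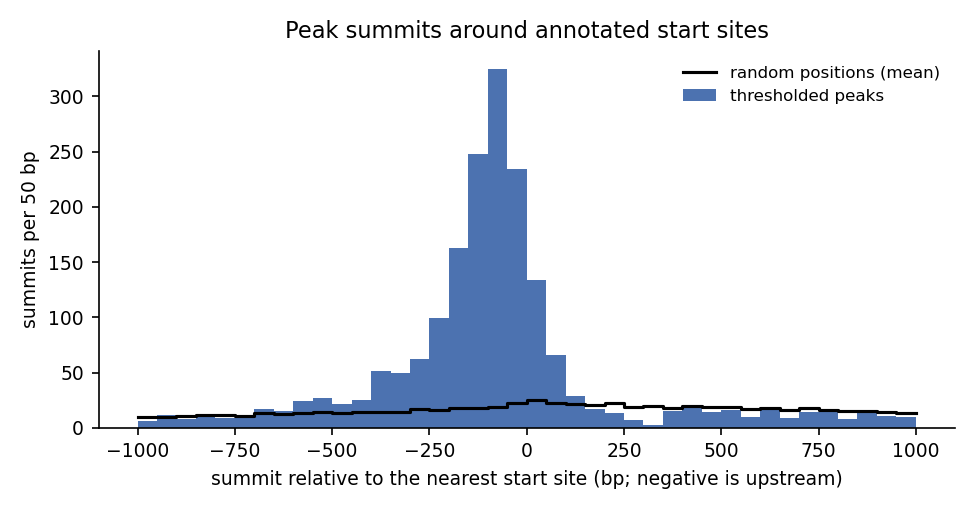
Number of thresholded summits per 50 bp (bars) by distance to the nearest annotated start site in bp, negative values being upstream, with the mean of random positions on the same chromosomes (line). The median promoter summit lies at -88 bp.

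Promoter peaks were found at 2010 of 13945 protein-coding genes (14.4%). The highest peaks of replicate 2 alone gave 14.6% and those of replicate 4 alone 13.7%. Among 33 gene lists fixed before the data were examined, 13 differed from the other genes in the share of members with a promoter peak (2-sided Fisher's exact test, Benjamini-Hochberg adjusted over the lists), 7 with a higher share and 6 with a lower share. Neighbouring genes can share a peak, so genes are not fully independent in these tests. A gene with more annotated start sites also has more chances to be counted. The number of start sites per gene was not adjusted for, so the shares are per gene and not per promoter.

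Genes for ribosomal proteins and for translation initiation and elongation factors carried peaks more often than other genes, while those for aminoacyl-tRNA synthetases did not pass the test. Of 86 genes for cytosolic ribosomal proteins, the proteins of the main cellular ribosome, 52 had a promoter peak (60.5%, exact interval 49.3 to 70.8%), against 14.1% of other protein-coding genes (log2 odds ratio 3.21, adjusted exact p = 2.17e-21). The highest of these peaks were at RpL7 (signal 353), RpS27 (300), RpL23A (288) and RpL34b (277), with summits 8 to 117 bp from a start site. The share was 66.3% with replicate 2 alone and 50% with replicate 4 alone, and the difference from other genes passed the threshold under each alternative tried. Of 73 genes for mitochondrial ribosomal proteins, 22 had a peak (30.1%, log2 odds ratio 1.38, adjusted exact p = 0.00239), led by mRpS10 (signal 803), mRpL41 (749), mRpS23 (744, a peak shared with CenG1A) and mRpL23 (411). Translation initiation and elongation factors had peaks at 15 of 51 genes (29.4%, log2 odds ratio 1.34, adjusted exact p = 0.0142). They were led by eIF6 (454), eEF1gamma (287), eIF4EHP (168) and eIF1 (156, shared with RpL28). The mitochondrial call was lost with replicate 4 alone (log2 odds ratio 0.97, adjusted exact p = 0.0751), among the 1379 highest peaks (0.99, 0.241) and with each peak given to its nearest start site (0.71, 0.331). Genes with an unthresholded peak are here those with a promoter peak of any rank in the pooled list, thresholded peaks included. They were 7634 protein-coding genes, 26.3% of them with a thresholded peak. When only these genes were compared, the mitochondrial and translation factor calls were lost (log2 odds ratios 0.68 and 1.09, adjusted exact p = 0.285 and 0.145).

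Genes for chromatin and cell cycle regulators also carried peaks more often. Insulator and promoter-binding architectural proteins, which organise chromosome domains, had peaks at 10 of 21 genes (47.6%, log2 odds ratio 2.44, adjusted exact p = 0.00137). Among them were Chro (712), Trl, the GAGA factor gene (183), Cp190 (172) and Dref (154, shared with RpL13). The peak at Cp190 had no summit within 100 bp in the list of replicate 4, although the highest peaks of each replicate alone included one within 500 bp of a Cp190 start site. Polycomb and trithorax group genes, which maintain gene silencing or activity, had peaks at 12 of 31 (38.7%, log2 odds ratio 1.93, adjusted exact p = 0.00279), led by ph-p (781), Bap60 (126), fs(1)h (111) and brm (108). DNA replication and cell cycle genes had peaks at 14 of 48 (29.2%, log2 odds ratio 1.33, adjusted exact p = 0.0188), led by Dp (166), dpa (150), dup (118) and Cdk7 (96.7, shared with the splicing factor gene snf). Ecdysone response genes had peaks at 6 of 15 (40%, log2 odds ratio 2.03, adjusted exact p = 0.0352), led by Eip75B (209), the receptor gene EcR (81.1), ftz-f1 (80.8) and usp (79.9). With either replicate alone the ecdysone call was lost (log2 odds ratio 1.72, adjusted exact p = 0.104 without replicate 2 and 0.72, 0.706 without replicate 4). The cell cycle call was lost without replicate 2 (1.11, adjusted exact p = 0.0908). Among the 1379 highest peaks the Polycomb (0.97, adjusted exact p = 0.754), cell cycle (-0.12, 1) and ecdysone calls (0.30, 1) were lost. With a window of 250 bp the cell cycle (log2 odds ratio 1.20, adjusted exact p = 0.0678) and ecdysone calls (1.54, 0.217) were lost, and with 1000 bp the ecdysone call (1.79, 0.0664). With each peak given to its nearest start site, the insulator (log2 odds ratio 1.90, adjusted exact p = 0.0506), cell cycle (1.10, 0.147) and ecdysone calls (1.80, 0.147) were lost. All 4 of these calls were lost among genes with an unthresholded peak (log2 odds ratios 1.63, 1.09, 0.41 and 1.49, adjusted exact p = 0.0865, 0.192, 0.701 and 0.272 in the order given).

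The other 6 lists past the threshold had few promoter peaks. Odorant, gustatory and ionotropic receptor genes had 0 peaks at 179 genes (exact interval up to 2.04%, adjusted exact p = 2.2e-11), cuticle protein genes 0 at 118 (up to 3.08%, adjusted exact p = 1.85e-07) and the replication-dependent histone genes 0 at 111 (up to 3.27%, adjusted exact p = 5.42e-07). No histone gene had a promoter peak in the pooled list either, and these genes are near-identical repeated copies. Whether a peak can be placed at such copies was not tested, so the 0 histone genes do not show a lack of binding. The copies also count as separate genes in the test, although they are not independent. Male-specific transcripts and accessory gland proteins had 1 peak at 60 genes (1.67%, log2 odds ratio -2.75, adjusted exact p = 0.0049), at Sfp26Ad, where the summit lay in the 5' UTR of Gpdh1. This list also holds the cuticle protein gene Acp65Aa. Genes for tRNAs had peaks at 11 of 290 (3.79%, against 12.1% of other genes of all classes, log2 odds ratio -1.74, adjusted exact p = 1.01e-05). They were led by tRNA:Tyr-GTA-1-8 (signal 338, in an intron of CG8036 and p), tRNA:Gln-TTG-2-1 (165), tRNA:His-GTG-1-3 (152) and tRNA:Phe-GAA-1-2 (134, shared with RpL17). Genes for snoRNAs had peaks at 12 of 269 (4.46%, log2 odds ratio -1.50, adjusted exact p = 0.000207). These were led by snoRNA:U49:66Da (194, shared with RpL14), snoRNA:Psi28S-2949 and snoRNA:Or-aca5 (188, a shared peak) and snoRNA:Or-CD11a (156, shared with eIF1 and RpL28). Among non-coding RNA genes outside the small RNA classes the share was 3.93%, against 14.4% of protein-coding genes. The tRNA and snoRNA lists were not tested against non-coding genes alone. Among genes with an unthresholded peak, the cuticle, tRNA and snoRNA calls held (adjusted exact p = 0.048, 1.76e-08 and 0.0447). The receptor call was lost there with 15 members left, none with a thresholded peak (log2 odds ratio -3.47, adjusted exact p = 0.0865), the male-specific difference was gone (-0.10, 1), and no histone gene was left to test. The snoRNA difference was gone with a window of 1000 bp (log2 odds ratio 0.045). Among the 1379 highest peaks the male-specific call (log2 odds ratio -3.35, adjusted exact p = 0.0563) and the snoRNA call (-1.09, 0.061) were lost.

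The other 20 lists did not pass the test. Patterning genes had shares near or below that of all genes, with 4 of 30 segmentation genes (bowl, 246, and nkd, 113, the highest), 2 of 26 dorsoventral genes (ush, 71.5, with no summit within 100 bp in replicate 4, and tin, 70.6), 0 of 8 Hox genes and 2 of 15 genes of the E(spl) complex and Bearded family (E(spl)m3-HLH, 176, and E(spl)m7-HLH, 98.3). Tissue lists likewise did not pass. Among them were 3 of 21 neurogenic genes (numb, 136, and N, 91.6), 2 of 23 neuron genes (elav, 293, and Nrx-1, 135, with no summit within 100 bp in replicate 2, where another peak lay within 500 bp of one of its start sites), 3 of 12 glial genes (moody, 310, and nrv2, 80.7), and 1 of 25 muscle genes (sls, 192). There were also peaks at 2 of 22 blood and fat body genes (LanA, 82.4, and ush), 3 of 19 trachea, gut and salivary gland genes (fkh, 176, and bnl, 113) and 4 of 18 germline genes (bgcn, 146, and orb, 97.6). The other housekeeping lists did not pass either, with 5 of 32 proteasome genes (Rpn5, 158, and Rpn3, 128), 11 of 76 oxidative phosphorylation genes (ND-ASHI, 207, and ND-MWFE, 198), 7 of 32 aminoacyl-tRNA synthetase genes (SerRS, 227, and IleRS, 142) and 5 of 29 splicing factor genes (SF2, 98.3, and snf, 96.7). Heat shock and chaperone genes had peaks at 7 of 24 (Hsp83, 266, and Hsp27, 152; adjusted exact p = 0.168), signalling components at 9 of 43 (spi, 300, and hpo, 139), snRNA genes at 5 of 32 (snRNA:U6:96Ab and snRNA:U6:96Ac, 125, a shared peak) and dosage compensation genes at 0 of 6. The list of chorion and vitelline membrane proteins had 1 of 17, which was Cp190. Its name pattern had taken in Cp190, an insulator protein, and Cp110, which are not chorion genes, so no chorion or vitelline membrane gene in the list had a promoter peak.

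**Figure D3:**
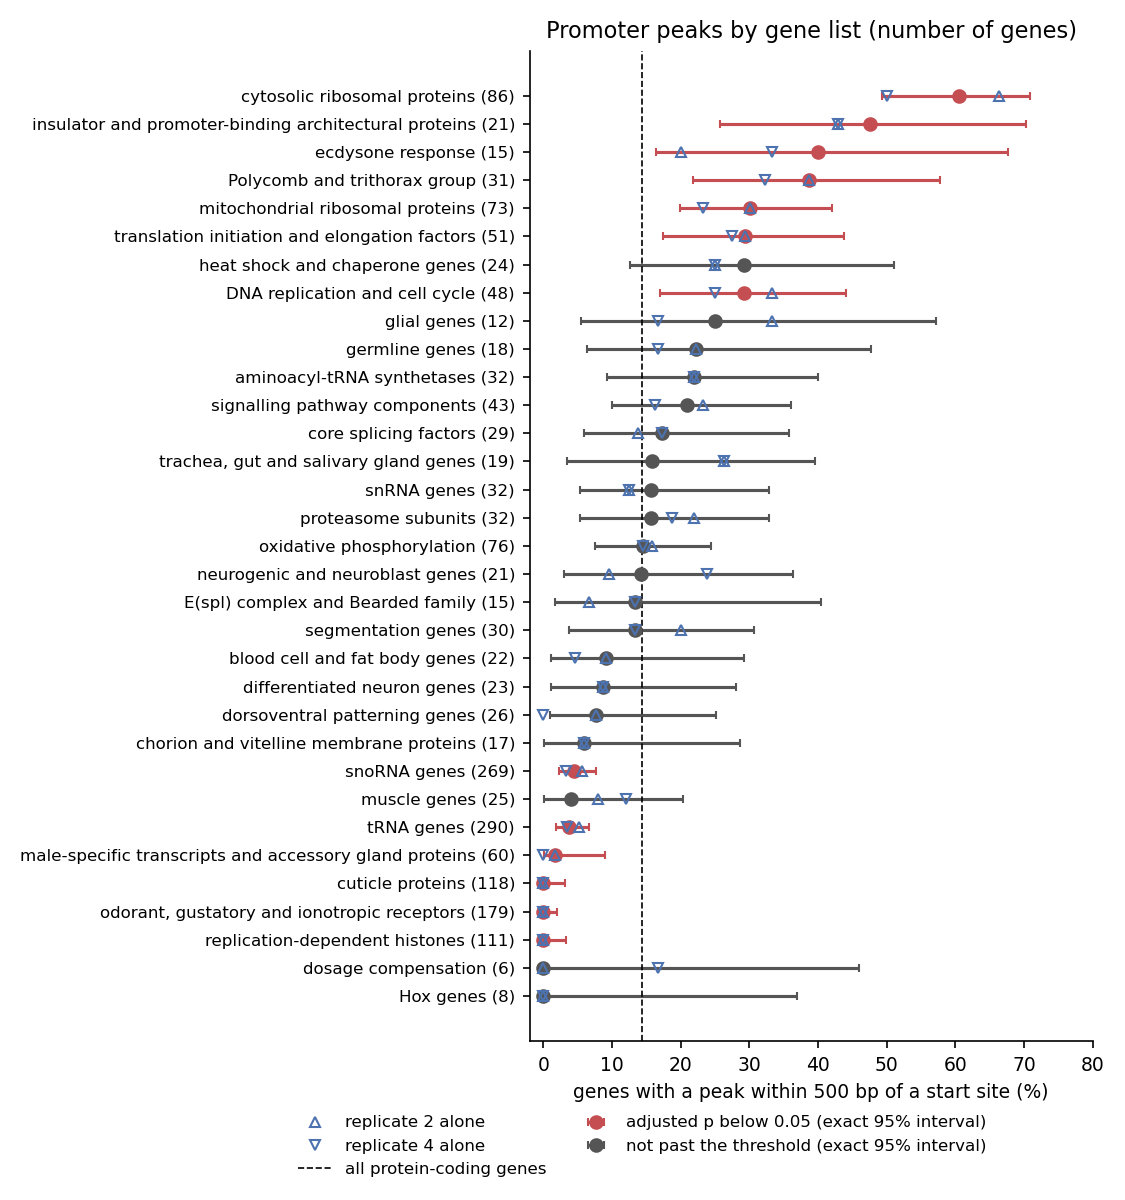
Percent of the genes of each list (number of genes in brackets) with a thresholded summit within 500 bp of a start site, with exact 95% intervals (filled circles, red where the adjusted p is below 0.05) and the values from the 2758 highest peaks of each replicate alone (triangles). The dashed line is the 14.4% of all protein-coding genes, and cytosolic ribosomal protein genes stand highest at 60.5%.

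Peaks were spread over the large chromosome arms in proportion to their length and were scarce on chromosome 4, the small and largely heterochromatic autosome. Chromosome 4 held 8 of 2758 peaks (0.29%, exact interval 0.125 to 0.571%), against 1.01% of the length of the 6 arms, a ratio of 0.288 (exact binomial test, 2-sided, adjusted exact p = 0.00013). Against its 0.776% of annotated start sites the ratio was 0.374 (adjusted exact p = 0.00923). Arms 2L, 2R, 3L, 3R and X had ratios to length between 0.971 and 1.08 and did not pass the test, and 2R had a ratio of 0.892 to its share of start sites (adjusted exact p = 0.0106). Among the 1379 peaks with the highest signal, chromosome 4 had a ratio of 0.36 that did not pass the threshold (adjusted exact p = 0.084).

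The sequence under the peaks held elements known from promoters of broadly expressed genes. The site of the factor Dref, TATCGATA, was present within 100 bp of 127 summits (4.6%) and in 0.508% of windows 1000 bp away (log2 odds ratio 3.20, exact binomial test on discordant peaks, adjusted exact p = 1.22e-22). Core promoter motif 1, the site of M1BP, was at 1.6% of summits against 0.218% (log2 odds ratio 2.80, adjusted exact p = 1.36e-07), and motif 7 at 6.82% against 1.92% (log2 odds ratio 1.89, adjusted exact p = 2.71e-19). Motif 6 (0.653% against 0.181%, log2 odds ratio 1.76, adjusted exact p = 0.0203) and the core of the Su(Hw) insulator site (0.834% against 0.29%, log2 odds ratio 1.48, adjusted exact p = 0.0171) completed the 5 largest increases. The shorter core of BEAF-32, CGATA, the TATA box and the GATA site were also more frequent, at 30.8%, 9.03% and 7.9% of summits against 21.5%, 6.27% and 5.95%. The Sp/KLF GC box (1.7% against 4.75%), the CTCF core (5.95% against 9.43%) and the downstream promoter element (75.6% against 80.7%) were less frequent, and the remaining 10 of 21 motifs did not pass the test. Among the 1379 peaks with the highest signal, the calls of motif 1 (log2 odds ratio 1.23, adjusted exact p = 0.343), motif 6 (0.45, 0.911), the GATA site (0.29, 0.387) and the CTCF core (-0.51, 0.0564) were lost. That of the Su(Hw) core was lost with a larger log2 odds ratio (2.21, adjusted exact p = 0.059) in fewer peaks. The TATA box and GATA site calls were also lost with either replicate alone, and that of motif 6 without replicate 2 (log2 odds ratio 1.84, adjusted exact p = 0.0671) and with windows of 50 bp (1.72, 0.1004). The GAGA repeat, which did not pass (4.35% against 3.95%, log2 odds ratio 0.14), passed without replicate 2 (0.48, adjusted exact p = 0.023) and without replicate 4 (0.54, 0.0163). It also passed with windows of 200 bp (0.93, adjusted exact p = 4.25e-12) and with flanks 2000 bp away (0.60, 0.0109).

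Part of this was shared by promoters without peaks. When promoter peaks were set against 20209 start sites with no thresholded peak within 1000 bp, motif 7 (10.7% against 4.96%, log2 odds ratio 1.20, Fisher's exact test, adjusted p = 2.89e-17), the Dref site (7.64% against 4.93%, log2 odds ratio 0.68, adjusted exact p = 6.2e-05) and the BEAF-32 core (37.5% against 33.7%, log2 odds ratio 0.24, adjusted exact p = 0.00885) were still more frequent. Motif 1 (2.69% against 2.5%) and motif 6 (1.07% against 1.18%) did not pass the test. The motifs that were less frequent at summits than in flanks did not pass here either. They were the Sp/KLF GC box (1.75% against 2.25%, adjusted exact p = 0.378), the CTCF core (5.76% against 6.37%, 0.546) and the downstream promoter element (76.4% against 78.2%, 0.268). Against sequence upstream of the start sites with no peak, a control added after seeing the data, motif 1 did pass (2.69% against 1.77%, log2 odds ratio 0.63, adjusted exact p = 0.0359). In the comparison with the start sites themselves, the TATA box (8.52% against 11.3%, adjusted exact p = 0.00229) and the initiator (39.8% against 50.9%, adjusted exact p = 1.55e-16) were less frequent at the peaks. Where start sites lie close together the control windows overlap. These tests, like those of 8-base sequences against start sites, therefore count some sequence more than once. The control windows of that comparison were centred on the start site. Peak windows were centred on the summit, with a lower quartile 168 bp upstream, so many did not reach the start site. Window placement alone can therefore lower the share of elements that lie there, and bound promoters cannot be said to hold fewer.

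**Figure D4:**
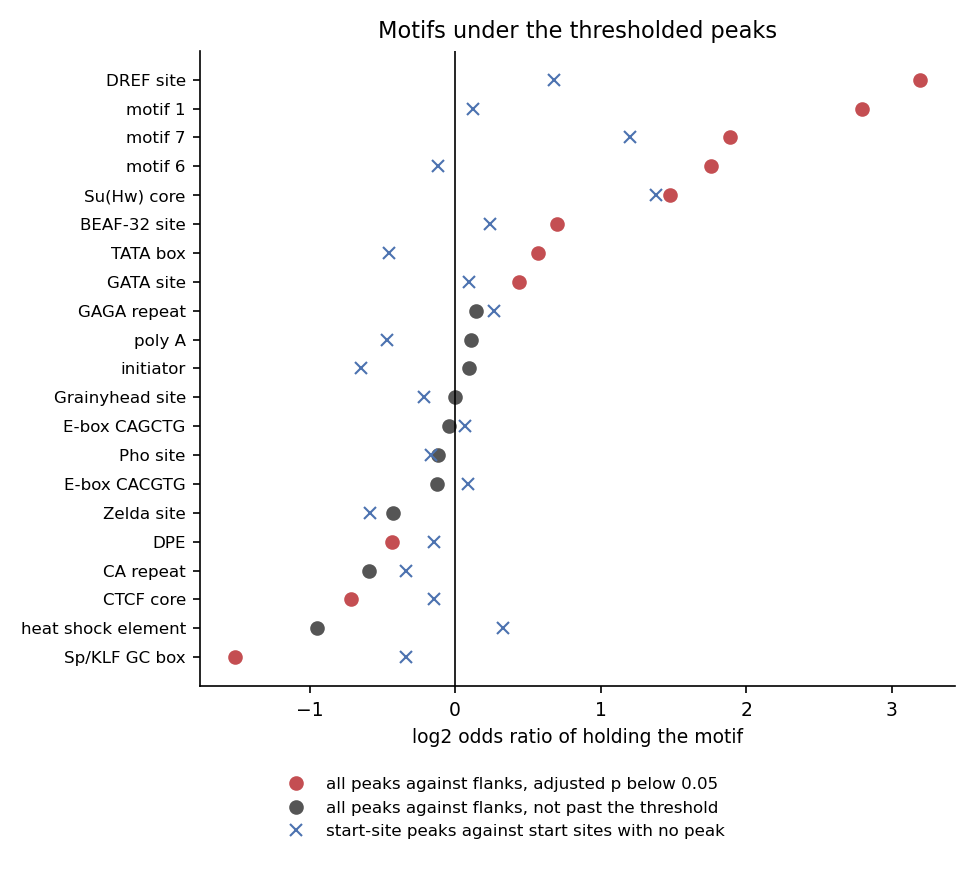
Log2 odds ratio of holding each motif within 100 bp of the summit, for all thresholded peaks against flanks 1000 bp away (circles, red where the adjusted p is below 0.05) and for promoter peaks against start sites with no peak (crosses). The Dref site falls from 3.20 to 0.68 between the comparisons, and motif 7 from 1.89 to 1.20.

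Of 32896 possible 8-base sequences, with reverse complements merged, 1147 were more frequent and 1206 less frequent at summits than in flanks (2-sided Fisher's exact test, Benjamini-Hochberg adjusted). With 0.5 added to each count, which lowers ratios from few windows, the largest ratios were those of CGATAGTC (28 of 2758 summits against 6 of 5516 flank windows, ratio 8.77), ACTGAGAG (65 against 15, ratio 8.45), CACTGAGA (95 against 23, ratio 8.13, adjusted exact p = 3.92e-22), GCGCTAGA (17 against 4, ratio 7.78) and ACCGCTAG (9 against 2, ratio 7.6, adjusted exact p = 0.0261). Among the 1379 highest peaks the calls of CGATAGTC (adjusted exact p = 0.503), GCGCTAGA (0.164) and ACCGCTAG (0.52) were lost. Without replicate 2 the call of ACCGCTAG was lost (adjusted exact p = 0.26), and without replicate 4 that of GCGCTAGA (0.129). Against start sites with no peak, CACTGAGA and GCGCTAGA passed (adjusted exact p = 0.000495 and 0.00277), and ACTGAGAG (0.238), CGATAGTC (0.224) and ACCGCTAG (0.829) did not. CACTG, read on either strand, was contained in 76 of the 1147 more frequent sequences. Against start sites with no peak, 590 sequences were more frequent, and CAACACTG had the smallest p (97 of 1596 promoter peaks, 6.08%, against 1.72%, adjusted exact p = 2.09e-18). Summits were poorer in G and C than their flanks, with a mean of 37.2% (SD 6.95 across peaks) against 43.1% (SD 7.21), a difference of -5.83 percentage points (SE 0.184), and 74.4% of peaks lay below their own flanks.

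**Figure D5:**
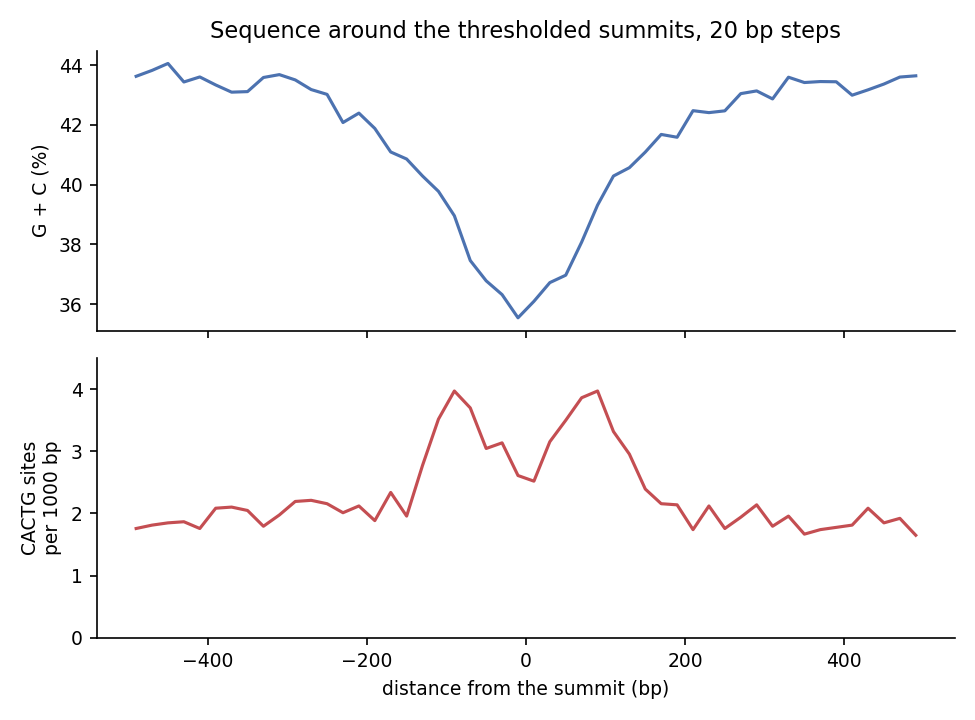
G and C content in percent (upper panel) and CACTG sites on either strand per 1000 bp (lower panel) in 20 bp steps around the 2758 thresholded summits. G and C content is lowest at the summit, at 35.5%, and CACTG sites are densest at 80 to 100 bp on each side, at 3.97 per 1000 bp.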

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

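The comparisons with each replicate alone, with genes that hold an unthresholded peak and with the share of start sites were planned, and the other tests in this part, and the use of all of them to weigh these patterns, were chosen after seeing the data. The comparisons above did not use the peaks of the dm3 lists that lie off the 6 chromosome arms, on heterochromatic, unplaced or mitochondrial sequences: there were 51 in the pooled list, 39 in the list of replicate 2 and 80 in that of replicate 4, and 0 in the thresholded list. The highest of them ranked 6644 in the pooled list, 574 in replicate 2 and 5348 in replicate 4.

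The first pattern weighed was the high share of cytosolic ribosomal protein genes with promoter peaks, 60.5%. In 7 other lists taken as broadly expressed, 79 of 341 genes had a promoter peak (23.2%, exact interval 18.8 to 28.0%). They were the proteasome, oxidative phosphorylation, splicing, aminoacyl-tRNA synthetase, mitochondrial ribosomal protein, translation factor and cell cycle genes. The highest upper bound among the 3 of these lists that passed was 44.1%, below the lower bound of 49.3%. These lists also hold paralogs such as COX4L and eIF4E3, and transcript levels were not analysed, so broad expression as such is not excluded. Peaks of a single replicate did not account for the high share of cytosolic ribosomal protein genes, as the lower share, in replicate 4, was 50% (interval 39.0 to 61.0%). Neither did the presence of any unthresholded peak, since the log2 odds ratio was 2.21 among genes that had such a peak. An effect of very high transcription on precipitation remains open, because transcript levels and the control were not analysed here. The design gives no biological explanation, so none was tested.

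The second pattern was the sequence CACTG, found within 100 bp of 48.3% of summits and in 31.6% of flank windows, a ratio of 1.53 (95% interval 1.45 to 1.62). Base composition does not account for it as a whole, since the 59 other 5-base sequences made of the same bases had a median ratio of 0.839, below the CACTG interval widened for its choice out of 512 sequences (1.37 to 1.71), but CTAGC, at 1.41, lay within that interval. Without windows that hold CANCNCTR, a shorter form of motif 7, or motif 1, elements that can contain it, the ratio was 1.53 (1.43 to 1.63), and that of CTAGC was 1.32. The ratio was 1.74 (1.60 to 1.89) at peaks more than 500 bp from annotated start sites, where sequence near those sites does not give it. Start sites missing from the annotation are not excluded there. At promoter peaks, against sequence upstream of start sites with no peak, the ratio was 1.40 (1.32 to 1.48). A candidate explanation is a sequence preference of the tagged protein or of a partner, a hypothesis found and examined on the same peaks. The density of CACTG sites did not peak at the summit, with 2.86 per 1000 bp within 40 bp and 3.46 at 41 to 140 bp. By rank CACTG was in 49.2% of windows in ranks 1 to 500, 48.0% in the thresholded ranks after 1000, 39.7% in ranks 2759 to 10000 and 31.4% in the last 10000. Words that contain it differed over ranks 1 to 500, 501 to 1000 and the thresholded ranks after 1000. CCACTGTG was in 7%, 2.8% and 3.47% of windows, and CAACACTG in 2%, 3.8% and 4.49%.

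The third pattern was the scarcity of peaks on chromosome 4. Low peaks were called on that chromosome, with 439 of 27242 pooled-list peaks below the threshold (1.61%, exact interval 1.47 to 1.77%, against 1.01% of length). Most such peaks are background, so they cannot show whether high peaks could be called there as readily. Read coverage and the control were not analysed. The low number of start sites of chromosome 4 leaves a ratio of 0.374 (upper bound 0.735), and the higher of the 2 replicates alone had 0.363% of its peaks there. The scarcity therefore appeared among high peaks and not among low ones. No biological explanation is given by the design, and none was tested.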

How the results depend on the processing

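The control from start-site upstream sequence, the direct comparison of replicates, the chorion list without Cp190 and the family of lists without histones and snoRNAs were added after seeing the data. Replicate overlap (52.6 to 70.3% over its alternatives), rank correlation (rho 0.587 to 0.659) and promoter share (48.2 to 67.4%) stayed past their thresholds under each alternative, and the dm3 lists gave 2776 peaks, 64.2% overlap and rho 0.603. Keeping the 6 arms removed no peak, and without dm3 lengths only shares per arm were computed there. No paired analysis was possible because there is 1 group. The 1379 peaks with the highest signal gave 7 lists past the threshold in place of 13 (3 higher), 0 arms in place of 1, 6 motifs in place of 11 (4 higher) and 613 8-base sequences in place of 2353 (426 higher, 187 lower), with fewer peaks in each test. The log2 odds ratio of the cell cycle list turned there to -0.12. Each replicate alone gave 4 to 6 higher lists. Among genes with an unthresholded peak, 4 lists passed (1 higher, 3 lower), and with each peak given to its nearest start site 3 were higher. A window of 1000 bp turned the snoRNA list to 0.045. Start-site shares gave 2 arms. Windows of 50 bp gave 5 motifs lower in place of 3. Against start sites with no peak, 5 motifs (3 higher) and 741 8-base sequences (590 higher, 151 lower) passed. The log2 odds ratios of motif 6 (-0.11), the TATA box (-0.45) and the initiator (-0.65) turned. Against sequence upstream of them, 7 motifs passed (4 higher), and motif 6 (-0.25), the GATA site (-0.30), the TATA box (-0.68), the initiator (-0.66) and poly A (-0.50) turned. Over all alternatives, 60 values of single lists, arms, motifs and sequences lost the threshold and 11 passed it anew, 4 of these for the GAGA repeat. There were 1293 6-base (477 higher) and 113 10-base sequences (110 higher, 3 lower). The cause was not tested beyond what each setting's construction shows. Of 70 named genes, 14 had no promoter peak among the 1379, 5 without replicate 2, 4 without replicate 4 and 13 with a 250 bp window. Unknown read depth limits what the absence of a peak can show.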

Other observations

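The comparisons in this part were chosen after seeing the data, except that the count of head-to-head start sites was fixed before its result was seen, while its draws and the count by nearest start site were added afterwards. Some genes, several of them long, carried many peaks along their length. The protein-coding gene with the most thresholded summits inside it was ush, with 10 in 64341 bp, followed by CG1677 (124709 bp), CHES-1-like (27048 bp), kirre (394149 bp) and sbb (79099 bp) with 8 each, and by Hr4 and Raf with 7 each. Trl, at 13121 bp a far shorter gene, held 6, or 4.57 per 10000 bp. In all, 118 protein-coding genes held 3 or more summits and 21 held 5 or more. By gene class, 128 of 3261 non-coding RNA genes other than the small RNA classes (3.93%, exact interval 3.28 to 4.65%) and 3 of 268 pseudogenes (1.12%) had a promoter peak.

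The replicates differed in how high they ranked ribosomal protein genes. Of 47 promoter peaks at cytosolic ribosomal protein genes present in both lists, 40 ranked higher in replicate 2 (85.1%, exact interval 71.7 to 93.8%), with median ranks of 590 and 1314, against 741 of 1445 other promoter peaks (51.3%, interval 48.7 to 53.9%), with median ranks of 1309 and 1365. No other list was compared in this way.

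A hypothesis examined on these peaks was that promoters between head-to-head genes carry peaks more often. Of 5261 start sites with an opposite-strand start site within 500 bp upstream, 1286 had a thresholded summit within 500 bp (24.4%), against 1330 of 18322 other start sites (7.26%), a ratio of 3.37. Part of this is given by construction, since a peak between paired start sites counts for both, and 1000 draws of peaks placed at random start sites gave a mean ratio of 1.68 (highest 2.05). With each peak counted only for its nearest start site, 558 head-to-head start sites (10.6%) and 1005 others (5.49%) had one, a ratio of 1.93. Peaks placed at random start sites gave a mean of 0.998 (highest 1.23) and those placed at start sites of random genes 1.05 (highest 1.23), with a 1-sided permutation p = 0.000999 against each, the smallest possible. Head-to-head genes may be enriched for broadly expressed genes, which was not separated from arrangement here.

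The dip in G and C content at summits was -6.97 percentage points (SE 0.262) at promoter peaks and -4.27 (SE 0.242) at the 1162 peaks away from start sites, and 88 bp upstream of start sites it was -6.51 (SE 0.229) where a thresholded peak was present and -3.49 (SE 0.0818) where none was. By rank in the pooled list it went from -6.71 (SE 0.403) in ranks 1 to 500 to -0.786 (SE 0.106) in the last 10000. This dip was first examined for technical explanations and then left unweighed in favour of the ribosomal protein pattern. CACTG sites were less dense within 40 bp of the summit, at 2.86 per 1000 bp, than at 41 to 140 bp, at 3.46, and their density was 1.86 beyond 300 and up to 500 bp.

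Around the tagged gene, 12 pooled-list peaks lay within 10000 bp of the middle of CG12744, against a mean of 8.36 (SD 3.71) at 2009 other protein-coding genes with a promoter peak, of which 19.4% had as many. The numbers were 12 in replicate 2 (21.0% had as many) and 15 in replicate 4 (3.43% had as many). Distances of 5000, 20000 and 40000 bp were also looked at. For replicate 4, between 8.06% and 11.1% of the other genes had as many peaks at these, so that 10000 bp gave the lowest share of the 4 distances. Reads of the transgene cannot be told apart in these counts either.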
